A study of Rattus norvegicus with 6 samples.

How the data were processed

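Expression was measured with 1-colour Affymetrix rat arrays hybridised with biotin-labelled cRNA, from GLI1-transformed RK3E cells (4 arrays) and parental RK3E cells (2 arrays) grown in medium with serum, per the labels' protocols. The deposited values are intensity values on a linear scale, 1 per probe set and array, made with MAS5, per the submitters' processing notes; its version is not given in the sources used here. In MAS5 the probes of a set are combined into 1 background-adjusted signal and each array is scaled to a common mean. The 2% trimmed mean computed here was the same on each array to within rounding, as that scaling sets it, and the values were used as scaled. Array medians still ran from 568 to 697, and other scalings were tried as alternatives. Detection calls were not used here, and a low signal is therefore not called absent. The genome build is not given in the sources used here, and no coordinates are printed.

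The labels call the samples biological replicates, and they do not say how the cultures were kept apart. The p-values measure only the spread between these arrays, 2 of which come from 1 clone, and the labels do not say to which clone the first GLI1 array belongs; it was assigned to none. No pair of arrays held repeated columns: the highest number of probe sets with an identical value in any pair was 16.

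Signals below 1 were set to 1 and log2 was taken. Of 31099 probe sets, 57 control probe sets were left out, and of the remaining 31042 those with a mean log2 signal over the 6 arrays above the 40th percentile (8.33, a signal of 322) were tested, 18625 in all. Groups were compared with limma (lmFit, then eBayes with an intensity trend; version 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The comparison of 4 GLI1 arrays with 2 parental arrays had 4 residual degrees of freedom. A 3-level model (clone II, other GLI1 arrays, parental), with 3 residual degrees of freedom, gave clone II against parental, the other GLI1 arrays against parental, and clone II against the other GLI1 arrays. Errors beside group means are SDs between arrays, SEs belong to log2 differences, and folds are 2 raised to the log2 difference or to its size. In the text "rose", "fell" and "called" mean an adjusted p under 0.05.

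Gene names came from a table pairing probe sets with genes: 20826 of the 31042 probe sets had 1 gene symbol, 436 had several and 9780 had none. Of the single-symbol probe sets, 20758 were matched by gene identifier to a list of rat genes of the GRCr8 assembly, used only for names, with 0 changed symbols, and 68 kept the table's symbol. No gene was named from a probe set with several symbols. Ptch1 and Gli3 were not analysed here.

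The genes to be named were fixed by a rule: Gli1 and the measured genes of the Hedgehog list; the 12 genes of largest rise and the 12 of largest fall among those past the threshold with all GLI1 arrays on 1 side of both parental arrays and a higher group mean above the 60th percentile (log2 10.17); up to 4 called genes of smallest adjusted p from each list, and up to 2 of the minority direction; and up to 6 each way between clone II and the other GLI1 arrays. Where a gene had several probe sets, the one with the highest mean was used. Members of a list mentioned without a value, and a few named with a value that did not pass, were added after the values were seen. Of 118 named genes 25 had other tested probe sets, and 0 had a called one of opposite sign.

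The 26 gene lists covered Hedgehog components, reported GLI targets, Sonic hedgehog medulloblastoma markers, replication, mitosis, epithelial and mesenchymal genes, matrix, proteases, IGF, Wnt, TGF-beta and BMP, MAPK feedback, interferon, inflammation, glycolysis, cholesterol, p53, ER stress, oxidative stress, kidney, homeobox genes and markers of fibroblasts, endothelium, immune and neural cells. They were tested over 10240 genes, with 1 probe set per gene, using limma's camera with a preset inter-gene correlation of 0.01 and, beside it, an estimated correlation, and fry, which does not compare a list with other genes. Adjusted p-values of the lists are over the 26 lists. Some genes stand in several lists. The lists, the groups, the tests, the rule for named genes and most alternatives were fixed before the data were examined.

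The procedure was tested on simulated data of 18625 probe sets with 200 changed, in 20 runs. Values were drawn independently for each probe set and array, with the spread left by the 3-level model. For GLI1-transformed against parental cells, differences between clones were therefore left out, as was correlation between genes in every run. The shares below hold for such data only, and the simulated lists cannot show how either correlation setting behaves with correlated genes. For GLI1-transformed against parental cells it recovered 17.3% of 2-fold and 60.6% of 4-fold changes, and 4.60% of its calls were unchanged probe sets. For clone II against parental the shares were 0.60%, 30.3% and 2.68%, for the other GLI1 arrays against parental 0.60%, 29.5% and 1.79%, and for clone II against the other GLI1 arrays 0.25%, 30.9% and 3.41%. A simulated list of 30 genes among 10240 raised by 0.5 on the log2 scale was called in 20 of 20 runs with either correlation, and an unchanged list was called, at an unadjusted p under 0.05, in 1 run with the preset correlation and in 0 with the estimated one.

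Alternatives were quantile normalization, median centring, no filter, a filter at the 60th percentile, log2(value + 32), eBayes without the trend or with robust estimation, a 2-fold minimum, the replicate number as a block, each array left out in turn, clone II averaged to 1 replicate, the 3-level model and 1 probe set per gene. Added after seeing the data were the log2 GAPDH 3'/5' ratio as a covariate and the comparison without the 2 arrays of highest ratio. Leaving out a parental array, or these 2 arrays, keeps 1 parental array, so calls can be lost there without a smaller change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.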

Results

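Transcript levels were measured on 6 1-colour Affymetrix rat arrays in RK3E cells, a rat kidney epithelial line immortalised with an adenovirus early-region oncogene. Of these arrays, 4 carried RNA from RK3E cells transformed by GLI1, a zinc finger transcription factor at the end of the Hedgehog pathway, and 2 carried RNA from parental RK3E cells. By the labels, transformed foci were isolated and maintained as lines: 1 GLI1 array belongs to clone I, 2 belong to clone II and 1 has no clone named. Each array held 31099 probe sets and had the same 2% trimmed mean signal to within rounding. Median signal was 691 on the array with no clone named, 571 on clone I, 580 and 568 on clone II, and 647 and 697 on the parental arrays. The GAPDH 3'/5' signal ratio, a measure of RNA integrity, was 2.09 on the array with no clone named, 1.45 on clone I, 7.52 and 1.39 on clone II replicates 1 and 2, and 3.66 and 1.43 on parental replicates 1 and 2. Log2 signals correlated across probe sets at 0.911 to 0.926 among GLI1 arrays, at 0.930 between the parental arrays, and at 0.882 to 0.902 between the groups. Probe sets are not independent replicates. The number of arrays limits the precision of every value below.

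Gli1 itself was high in every GLI1 array and low in both parental arrays. Its log2 signal was 13.15 on the array with no clone named, 11.71 on clone I, 11.77 and 12.17 on clone II, and 5.17 and 6.50 on the parental arrays. The means were 12.20 ± 0.66 (SD, n = 4) and 5.84 ± 0.94 (SD, n = 2), an 82.4-fold rise (log2 6.36, SE 0.49, adjusted p = 0.000159, limma). The parental signal was dim, and the ratio became 51.9-fold when 32 was added to each value before the log. Whether the Gli1 probe set detects the introduced or the endogenous transcript is not given in the sources used here.

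Hhip, which encodes a membrane protein that binds Hedgehog ligands and is a known target of the pathway, rose 12.1-fold, from 7.43 ± 0.36 (SD, n = 2) to 11.02 ± 0.32 (SD, n = 4) on the log2 scale (SE of the difference 0.31, adjusted p = 0.000279). Of the 13 tested Hedgehog pathway genes, 2 rose (Gli1 and Hhip), 0 fell and 11 did not pass, with Gli1 counted although the cells were transformed by GLI1. Adjusted over the list alone the counts were also 2 and 0. The receptor gene Smo gave a log2 difference of -0.24 (adjusted p = 0.43), Gli2 0.14 (0.683), and Sufu -0.18 (0.797). The difference was -0.33 (0.618) for Boc, -0.66 (0.222) for Disp1, -0.13 (0.857) for Stk36, 0.09 (0.817) for Kif7 and 0.20 (0.674) for Spop. Kif3a gave 0.55 (adjusted p = 0.115), Ift88 0.45 (0.289) and the ligand gene Dhh 2.08 (0.084). The small differences of Sufu, Boc, Stk36, Kif7 and Spop change sign under some settings. Cdon, Shh, Ihh and Gas1 lay below the signal filter and were not tested. The list as a whole had a median log2 change of 0.14 and was not called (camera adjusted p = 0.181). Without clone II replicate 1 and parental replicate 1, the arrays of highest GAPDH ratio, it was called (0.0341), as it was by fry (0.0413).

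**Figure D1:**
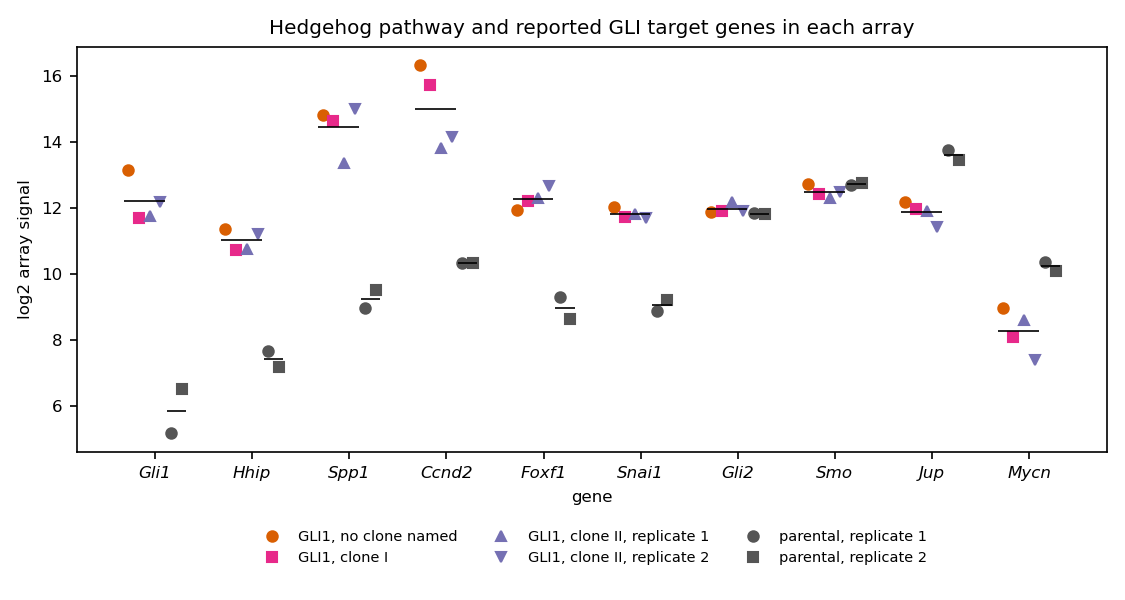
Log2 signal (vertical axis) of 10 genes on the 6 arrays, with a point per array and a line at each group's mean. Gli1 lies between 11.71 and 13.15 on the GLI1 arrays and at 5.17 and 6.50 on the parental arrays, while the group means of Smo differ by -0.24.

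The comparison of GLI1-transformed with parental cells, the one the study states, asks which transcripts differ once GLI1 has transformed the line. Itih3, which encodes a heavy chain of a serum protease inhibitor that binds hyaluronan, had the largest rise among genes named by the fixed rule, 795-fold (log2 9.63, SE 1.04, adjusted p = 0.000792). Here and for every gene below, 4 GLI1 and 2 parental arrays were compared. The neuropeptide gene Gal rose 120-fold (adjusted p = 0.000335), the homeobox gene Nkx6-1 115-fold (3.31e-06), and the POU factor gene Pou3f1 101-fold (0.0092). Rises were also found for Tmem132e, 96.8-fold (1.36e-05), the zinc finger gene Zfp423, 59.8-fold (0.000702), and Ntng1, which encodes an axon guidance protein, 49.4-fold (0.00369). The 3 other tested probe sets of Zfp423 did not pass, with log2 differences of -0.04 (adjusted p = 0.97), 0.41 (0.574) and 0.20 (0.802). Tmem119 rose 42.0-fold (1.18e-05), the secreted phosphoprotein gene Spp1 36.7-fold (0.000181), the imprinted RNA gene H19 35.1-fold (0.00193) and the cartilage collagen gene Col9a3 33.5-fold (0.000591). The largest fall was that of Lox, the enzyme that crosslinks collagen and elastin, 134-fold (log2 -7.07, SE 0.26, adjusted p = 3.31e-06). Fibrillar collagens and matrix genes fell with it: Col3a1 131-fold (6.99e-05), Loxl1 108-fold (0.000661), Mgp 83.1-fold (0.000615), Bgn 56.1-fold (0.00369), Col1a2 52.9-fold (1.36e-05) and Col1a1 45.4-fold (0.000919).

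Prss23, a serine protease gene, fell 83.1-fold (adjusted p = 9.44e-05), the caveolar coat gene Cav1 53.3-fold (4.37e-05), the protease inhibitor gene A2m 48.6-fold (0.0459), Tgfb3 46.2-fold (4.47e-05) and the small heat shock protein gene Cryab 39.0-fold (1.85e-05). With 32 added to each value before the log, dim signals gave smaller ratios: 286-fold for Itih3, 71.8-fold for Gal, 45.0-fold for Pou3f1, 37.7-fold for Zfp423, 26.1-fold for Ntng1 and 31.3-fold for A2m. The call of Pou3f1 was lost without parental replicate 1 (adjusted p = 0.0688) or 2 (0.0865), that of Bgn without parental replicate 1 (0.0574), and that of A2m without clone II replicate 1, parental replicate 1 (0.253) or parental replicate 2 (0.177), or with no filter (0.0578). Without parental replicate 2 the log2 rise of Ntng1 went from 5.63 to 3.69. The other 21 of these 24 genes of largest change stayed past the threshold with any 1 array left out.

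Among 18625 probe sets tested with limma, 1087 (833 named genes) rose and 1351 (845 named genes) fell at a Benjamini-Hochberg adjusted p under 0.05, and 16187 did not pass. The 4 GLI1 arrays lay entirely above or entirely below the parental arrays for 3544 and 3766 probe sets, 39.2% of those tested, where 13.3% would do so by chance. With every array centred on its median instead, 1454 rose and 944 fell, so that 60.6% of the calls were rises against 44.6% here. That centring moved the median of all tested probe sets from 0.005 to 0.165. Without the intensity trend 705 rose and 1090 fell, with a 2-fold minimum 617 and 1073. The counts were 228 risen and 282 fallen without parental replicate 1, 276 and 421 without parental replicate 2, and 599 and 900 without clone I. They were 145 and 167 without clone II replicate 1 and parental replicate 1, the arrays of highest GAPDH ratio.

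Cyclin D2 (Ccnd2), which drives entry into the cell cycle, rose 25.6-fold (log2 4.68, SE 0.63, adjusted p = 0.00213), the forkhead gene Foxf1 9.93-fold (0.000226) and Snai1, a repressor of epithelial genes, 6.84-fold (0.000181). They belong to a list of 27 tested genes reported elsewhere as targets of GLI factors, of which 9 rose, 6 fell and 12 did not pass (9 and 6 adjusted over the list alone). The others that rose were Spp1, Igfbp6, Ccnd1, Foxd2, Foxm1 and Rab34. Jup, which encodes the junction protein plakoglobin, fell by 1.73 on the log2 scale (adjusted p = 0.00225), the nuclear receptor gene Nr2f2 fell by 0.83 (0.0218), and Mycn, Bmp4, Fst and Hsd11b2 also fell. The list went both ways, its median was 0.35, and it was not called (camera adjusted p = 0.548). Part of it comes from earlier reports on GLI1-transformed cells, which can include this line, so its counts are not independent evidence of direction. It held 4 risen and 1 fallen genes without parental replicate 1, 5 and 1 without parental replicate 2, and 7 and 2 without clone I. The call of Nr2f2 was lost without either parental array (adjusted p = 0.2 and 0.0977) or with median centring (0.0693), and its other probe sets did not pass (log2 -0.55, adjusted p = 0.255, and -0.40, 0.572).

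The study set these profiles beside desmoplastic medulloblastoma, a cerebellar tumour; tumour samples were not analysed here, and only a list of marker genes was examined. Of 16 tested markers of medulloblastoma of the Sonic hedgehog kind, 5 rose (Gli1, Hhip, Ccnd2, Ccnd1 and Gab1), 2 fell and 9 did not pass, with the same counts adjusted over the list alone. Gli1 is counted there although the cells were transformed by GLI1, so its rise does not speak for likeness to the tumour. Eya1, a developmental phosphatase gene, fell by 2.63 on the log2 scale (SE 0.36, adjusted p = 0.00225), and Mycn, an oncogene often expressed in these tumours, fell by 1.97 (SE 0.47, adjusted p = 0.0258). The median was 0.04, and the list was not called (camera adjusted p = 0.641). With either parental array left out 3 rose and 1 fell, and the call of Mycn was lost (adjusted p = 0.209 without replicate 1, 0.124 without replicate 2), as it was without clone I (0.0627).

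Of 31 tested extracellular matrix genes, 0 rose, 18 fell and 13 did not pass (0 and 19 adjusted over the list alone). The median log2 change was -1.37. Besides Lox, Col3a1 and Col1a2, the fibronectin gene Fn1 fell by 2.54 (SE 0.23, adjusted p = 0.000306), where this and all changes below given without a fold are log2 differences. The basement membrane collagen gene Col4a1 gave a log2 difference of 0.49 (adjusted p = 0.278). Of 18 tested matrix proteases and inhibitors, 0 rose, 9 fell and 9 did not pass (0 and 10 adjusted over the list alone). The list had a median of -1.08. The aggrecanase gene Adamts5 (log2 -4.46, adjusted p = 0.00124), Mmp23 (-2.18, 0.00108), the plasminogen activator gene Plat (-2.02, 0.0011) and the cathepsin gene Ctsb (-1.11, 0.00221) fell. The inhibitor genes Timp1, Timp2 and Serpine2 were among those that fell. Both lists were called (camera adjusted p = 5.29e-10 and 5.75e-07), and neither was with an estimated correlation (adjusted p = 0.225 and 0.0959). Of 5 tested fibroblast markers, 3 fell (Col3a1, Col1a1 and Ogn) and 2, Fbln1 and Pdgfra, did not pass, with the same counts adjusted over the list alone. Col3a1, Col1a1 and Fbln1 are also matrix list members. The fibroblast list's median was -4.22 (camera adjusted p = 0.00548; adjusted p = 0.225 with an estimated correlation). The matrix list held 8 fallen genes without parental replicate 1 and 12 without parental replicate 2, the protease list 5 and 6, and the fibroblast list 2 and 2. Ogn (adjusted p = 0.0456) lost its call without any 1 of the 4 arrays outside clone II or with no filter (0.056). Mmp23 had another probe set that did not pass (log2 -0.57, adjusted p = 0.439). Outside these lists the cartilage collagen genes Col9a3, named above, and Col9a2 (adjusted p = 0.00315), chosen after its values were seen, rose.

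Of 19 tested mesenchymal and cytoskeletal genes, 1 rose, 12 fell and 6 did not pass (1 and 14 adjusted over the list alone). Here the median was -1.97 (camera adjusted p = 2.05e-08; adjusted p = 0.0959 with an estimated correlation). The tropomyosin gene Tpm2 fell by 2.12 (SE 0.19, adjusted p = 0.000312), and Ankrd1 (-3.88, 0.000431) and the N-cadherin gene Cdh2 (-1.97, 0.00168) fell with it. The gene that rose was Snai1, and the smooth muscle genes Acta2, Tagln and Cnn1 were among those that fell. The fallen genes numbered 7 without parental replicate 1 and 6 without parental replicate 2. Among 15 tested epithelial junction and keratin genes, 2 rose, 4 fell and 9 did not pass (3 and 4 adjusted over the list alone). The median log2 change was -0.48, and this list was not called (camera adjusted p = 0.295). The claudin gene Cldn1 rose by 1.95 (adjusted p = 0.014) and the integrin gene Itga6 by 0.92 (0.0228), while Jup, the desmoplakin gene Dsp (-1.12, 0.00702) and the tight junction gene Tjp1 (-0.69, 0.0203) fell. With either parental array left out this list held 0 risen genes and 1 fallen gene, and the calls of Cldn1, Itga6, Dsp and Tjp1 were lost. Itga6 lost its call without clone I too, and Tjp1 with median centring (adjusted p = 0.0918). Other probe sets of Itga6 did not pass, at log2 differences of -0.55 (0.386), 0.39 (0.478) and 0.80 (0.0645).

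In the TGF-beta and BMP signalling list of 28 tested genes 2 rose, 19 fell and 7 did not pass (2 and 20 adjusted over the list alone). The list had a median of -1.35 (camera adjusted p = 3.34e-08; adjusted p = 0.0959 with an estimated correlation). Tgfb3 fell by 5.53 (SE 0.34, adjusted p = 4.47e-05), and Tgfb2 (-3.32, 0.000335) and the inhibitory Smad gene Smad7 (-3.63, 0.000731) also fell. Bmp7 rose by 3.42 (0.000168) and Id4, an inhibitor of helix-loop-helix factors, by 2.15 (0.0035). In the Wnt list of 23 tested genes 1 rose, 5 fell and 17 did not pass (3 and 9 adjusted over the list alone). Here the median was -0.80 (camera adjusted p = 0.00539; adjusted p = 0.348 with an estimated correlation). The receptor genes Fzd1 (-3.43, 9.06e-05) and Fzd4 (-2.98, 0.00112) fell. The secreted antagonist genes went apart: Sfrp4 fell by 4.80 (0.0011) and Wif1 rose by 3.68 (0.00087). The TGF-beta and BMP list held 7 fallen genes with either parental array left out, and 12 without clone I or without clone II replicate 2. The Wnt list held 9 fallen genes without the array that has no clone named, and was not called when the filter was set at the 60th percentile (camera adjusted p = 0.426). The named genes of both lists stayed past the threshold with any 1 array left out. Another probe set of Smad7 did not pass (log2 -1.01, adjusted p = 0.133).

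Of the 21 tested growth factor receptor and MAPK feedback genes, 0 rose, 6 fell and 15 did not pass (0 and 7 adjusted over the list alone). Those that fell included Egr1 (log2 -2.27, SE 0.34, adjusted p = 0.00379), Fos (-2.56, 0.0107), and the phosphatase genes Dusp1 (-2.12, 0.00576) and Dusp6 (-2.52, 0.00866). The list's median log2 change was -0.62 (camera adjusted p = 0.000589; adjusted p = 0.236 with an estimated correlation). The count of fallen genes was 0 without parental replicate 1 and 1 without parental replicate 2, and the other probe set of Dusp1 did not pass (log2 -0.83, adjusted p = 0.417). Developmental transcription factor genes that fell included Hoxa5 (-4.26, adjusted p = 0.000168), Sox4 (-1.80, 0.000822) and the Hox cofactor genes Meis1 (-1.81, 0.00156) and Meis2 (-1.57, 0.00164). In that list of 21 tested genes 0 rose, 7 fell and 14 did not pass (1 and 7 adjusted over the list alone). The list had a median of -0.35 (camera adjusted p = 0.00266; adjusted p = 0.144 with an estimated correlation). That median became -0.21 without clone II replicate 2. The list leaves out other homeobox genes, such as Nkx6-1 and Pou3f1, which rose, and Emx2, which fell. Of the 5 other probe sets of Sox4, 1 did not pass (log2 0.57, adjusted p = 0.368). Of 6 tested neural markers 2 fell, Map2 (-1.60, adjusted p = 0.00717) and Nes (-1.45, 0.0479), and 4 did not pass (0 risen and 5 fallen adjusted over the list alone). Here the median was -1.21 (camera adjusted p = 0.0131; adjusted p = 0.236 with an estimated correlation). Neither gene kept its call without parental replicate 1 or 2, nor Nes without clone II replicate 2, with median centring (adjusted p = 0.0589) or with no filter (0.0627). The neural list was not called without parental replicate 2 (camera adjusted p = 0.0574), with no filter (0.145) or with 32 added before the log (0.0543).

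Some replication and mitosis genes rose, by small amounts. Of 26 tested G1/S and DNA replication genes, 9 rose, 0 fell and 17 did not pass (11 and 0 adjusted over the list alone). The list's median log2 change was 0.47 (camera adjusted p = 8.07e-05; adjusted p = 0.225 with an estimated correlation). The origin recognition gene Orc1 rose by 1.78 (SE 0.31, adjusted p = 0.00723), the helicase genes Cdc45 by 1.05 (0.00695) and Gins1 by 0.98 (0.0077), and the uracil glycosylase gene Ung by 0.79 (0.0143). Of 27 tested G2/M genes, 7 rose, 0 fell and 20 did not pass (13 and 0 adjusted over the list alone). The list had a median of 0.55 (camera adjusted p = 0.000112; adjusted p = 0.515 with an estimated correlation). The mitotic kinase gene Aurkb rose by 1.31 (0.00648), Ube2c by 0.92 (0.00938), Bub1 by 0.82 (0.013) and Nusap1 by 0.80 (0.0123). The risen genes of the replication list numbered 1 without parental replicate 1, 2 without parental replicate 2, and 5 without clone I. Those of the mitosis list numbered 0, 2 and 4 in that order, 4 without clone II replicate 2 and 11 without the array that has no clone named. All 8 genes named here lost their call without 1 or both of the parental arrays in turn.

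Some genes of the interferon response rose, to different levels on different GLI1 arrays. The transporter gene Tap1, which feeds peptides to MHC class I, rose by 2.02 (SE 0.26, adjusted p = 0.0019), the ubiquitin-like gene Isg15 by 2.76 (SE 0.51, 0.00969), the chemokine gene Cxcl10 by 3.83 (SE 0.81, 0.0166) and the antiviral gene Rsad2 by 1.68 (SE 0.36, 0.0176). Isg15 was at log2 14.64 on the array with no clone named, 16.73 on clone I, 16.62 and 16.46 on clone II, and 13.30 and 13.41 on the parental arrays. Cxcl10 was at 12.48, 15.96, 15.55 and 15.32 on the GLI1 arrays in that order and at 10.77 and 11.22 on the parental arrays. Of 28 tested genes, 10 rose, 0 fell and 18 did not pass (13 and 0 adjusted over the list alone). Here the median was 0.97 (camera adjusted p = 1.88e-05; adjusted p = 0.319 with an estimated correlation). The number risen was 1 without parental replicate 1, 1 without parental replicate 2, 6 without clone I and 17 without the array that has no clone named. With either parental array left out Isg15, Cxcl10 and Rsad2 were no longer called, and Tap1 was.

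**Figure D2:**
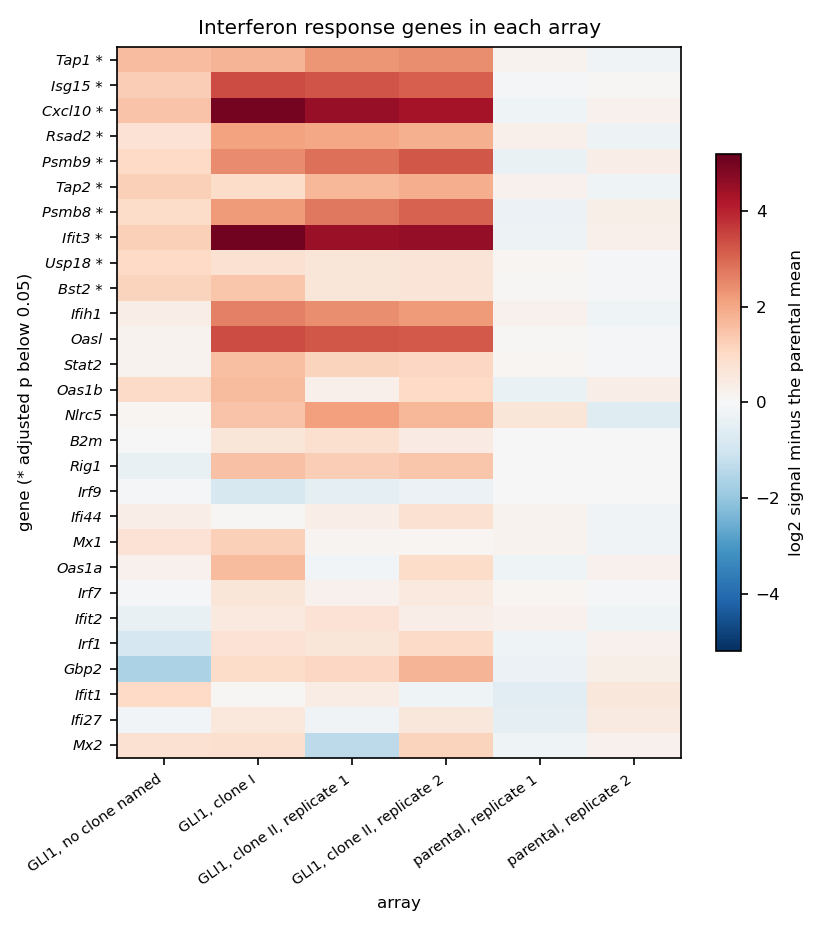
Log2 signal minus the parental mean (colour scale from -5.2 to 5.2) of the 28 tested interferon response genes on the 6 arrays, with an asterisk at genes of adjusted p under 0.05. The list's median against the parental mean was 0.54 on the array with no clone named, 1.46 on clone I, and 0.95 and 1.11 on clone II.

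Inflammatory genes went both ways. The chemokine gene Cxcl12 fell by 3.62 (SE 0.30, adjusted p = 0.000211) and the hyaluronan-binding gene Tnfaip6 fell by 1.53 (0.0424). The adhesion gene Icam1 rose by 1.94 (0.00107), the NF-kB inhibitor gene Tnfaip3 by 1.88 (0.0214) and Nfkb2 by 0.92 (0.035). Of 18 tested genes, 3 rose, 2 fell and 13 did not pass (7 and 2 adjusted over the list alone). The median log2 change was 1.13, and the list was not called (camera adjusted p = 0.083). With parental replicate 1, parental replicate 2 or clone I left out in turn, 1 gene rose and 1 fell, and Tnfaip3, Nfkb2 and Tnfaip6 lost their calls. Nfkb2 lost its call also without either array of clone II, and Tnfaip6 without clone II replicate 1, with quantile normalization (adjusted p = 0.0681), with median centring (0.068) and with no filter (0.0843). Without the array that has no clone named 9 rose and the list was called (camera adjusted p = 0.000762). Of 5 tested immune cell markers 1 fell, Cd14 (-1.83, adjusted p = 0.03), and 4 did not pass (1 risen and 1 fallen adjusted over the list alone). The immune list had a median of -0.25 and was not called (camera adjusted p = 0.564). Cd14 was not called without either parental array, clone I or clone II replicate 2. Of 4 tested endothelial markers 0 changed in limma, also adjusted over the list alone, and 0 had an unadjusted p under 0.05. Their median was -0.26 (camera adjusted p = 0.564).

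The glucose phosphorylating enzyme gene Hk2 rose by 3.23 (SE 0.58, adjusted p = 0.00819), the aldolase gene Aldoc by 1.60 (0.0155) and Pdk1, a brake on pyruvate oxidation, by 1.30 (0.0193). The stress gene Ndrg1 fell by 3.57 (0.00205). Of 26 tested glycolysis and hypoxia genes, 4 rose, 1 fell and 21 did not pass (9 and 1 adjusted over the list alone). Here the median was 0.64 (camera adjusted p = 0.00636; adjusted p = 0.65 with an estimated correlation). In the list of ER stress and amino acid response genes, the amino acid synthesis genes Asns and Psat1 rose by 1.66 (adjusted p = 0.0061) and 1.40 (0.00586), the cystine transporter gene Slc7a11 by 1.94 (0.0199) and the stress factor gene Ddit3 by 1.55 (0.0149), and the chaperone cofactor gene Dnajb9 fell by 1.22 (0.0416). Of these 24 tested genes, 6 rose, 1 fell and 17 did not pass (9 and 1 adjusted over the list alone). The list's median log2 change was 0.49 (camera adjusted p = 0.0171; adjusted p = 0.65 with an estimated correlation). That list was not called with quantile normalization (camera adjusted p = 0.0809), without parental replicate 2 (0.0683) or without the array that has no clone named (0.0602). Both lists held 0 risen genes without parental replicate 1 and 1 without parental replicate 2. The glycolysis list held 2 risen genes without clone I and 10 without clone II replicate 2. Of the genes named here, Ndrg1 alone kept its call with any 1 array left out. Dnajb9 lost its call also with median centring (adjusted p = 0.0517) and with no filter (0.0505), and the other probe set of Pdk1 did not pass (log2 -0.06, adjusted p = 0.932).

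The remaining lists were not called. Of 12 tested genes of the IGF axis, 2 rose, 1 fell and 9 did not pass (2 and 2 adjusted over the list alone). H19 rose as above, the binding protein gene Igfbp6 rose by 2.51 (adjusted p = 0.00446; 0.0681 without parental replicate 1) and the insulin receptor substrate gene Irs1 fell by 3.80 (0.0012). The list's median was 0.01, and its camera direction was down (adjusted p = 0.772). Of 8 tested kidney epithelium and nephron genes, 3 rose, 2 fell and 3 did not pass, with the same counts adjusted over the list alone and a median of 0.47 (camera adjusted p = 0.271). Bmp7 and Spp1 rose as above, and the chaperone gene Clu rose by 1.19 (0.00806; 0.111 without parental replicate 1). The renal homeobox gene Emx2 (-1.49, 0.0294) and the endocytic receptor gene Lrp2 (-1.09, 0.0437) fell, both losing the call without any 1 array other than the one with no clone named, and Lrp2 also with median centring (0.0577) or no filter (0.0687). Another probe set of Clu did not pass (log2 0.58, adjusted p = 0.39). The kidney list was called with the filter at the 60th percentile (camera adjusted p = 0.000331), where Bmp7, Spp1 and Clu were its only tested genes and the median was 3.42. Of 14 tested p53 targets, 2 rose, Bbc3 by 1.07 (0.00897) and Sesn2 by 1.30 (0.0227), and 12 did not pass (2 and 0 adjusted over the list alone). Another probe set of Sesn2 did not pass (log2 0.22, adjusted p = 0.849). The list had a median of -0.01 and a mean of 0.17 (camera up, adjusted p = 0.772). With either parental array left out 0 rose, and without the array that has no clone named 4 did. Of 21 tested oxidative stress and glutathione genes, 0 rose and 3 fell, also adjusted over the list alone, and 18 did not pass. Those that fell were Gpx1 (-1.51, adjusted p = 0.00287), Gsta4 (-1.34, 0.00641) and Gstm2 (-1.88, 0.0331). The median was 0.17 and the mean -0.12 (camera down, adjusted p = 0.711). The number fallen was 0 without parental replicate 1 and 1 without parental replicate 2. Without parental replicate 2 the change of Gstm2 was -1.19 (adjusted p = 0.274), and its call was lost also without parental replicate 1 (0.0524), clone I (0.0735) or clone II replicate 1 (0.057). Gsta4 lost its call without either parental array (0.0651 and 0.0745) and Gpx1 without parental replicate 1 (0.0502). Of 19 tested cholesterol synthesis genes 0 rose and 0 fell in limma, also adjusted over the list alone, and 6 had an unadjusted p under 0.05. Their median was 0.22 (camera adjusted p = 0.689). In all, 14 of 26 lists were called with the preset correlation and 0 with an estimated one. Fry, which asks whether a list's genes move on balance 1 way, also called 14, but not the same lists. It called the Hedgehog list, which holds Gli1 itself (adjusted p = 0.0413), and the kidney list (0.0227). Camera called neither of these. Fry did not call the glycolysis and ER stress lists (both 0.158). Its test for changes in either direction called 25 of 26.

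**Figure D3:**
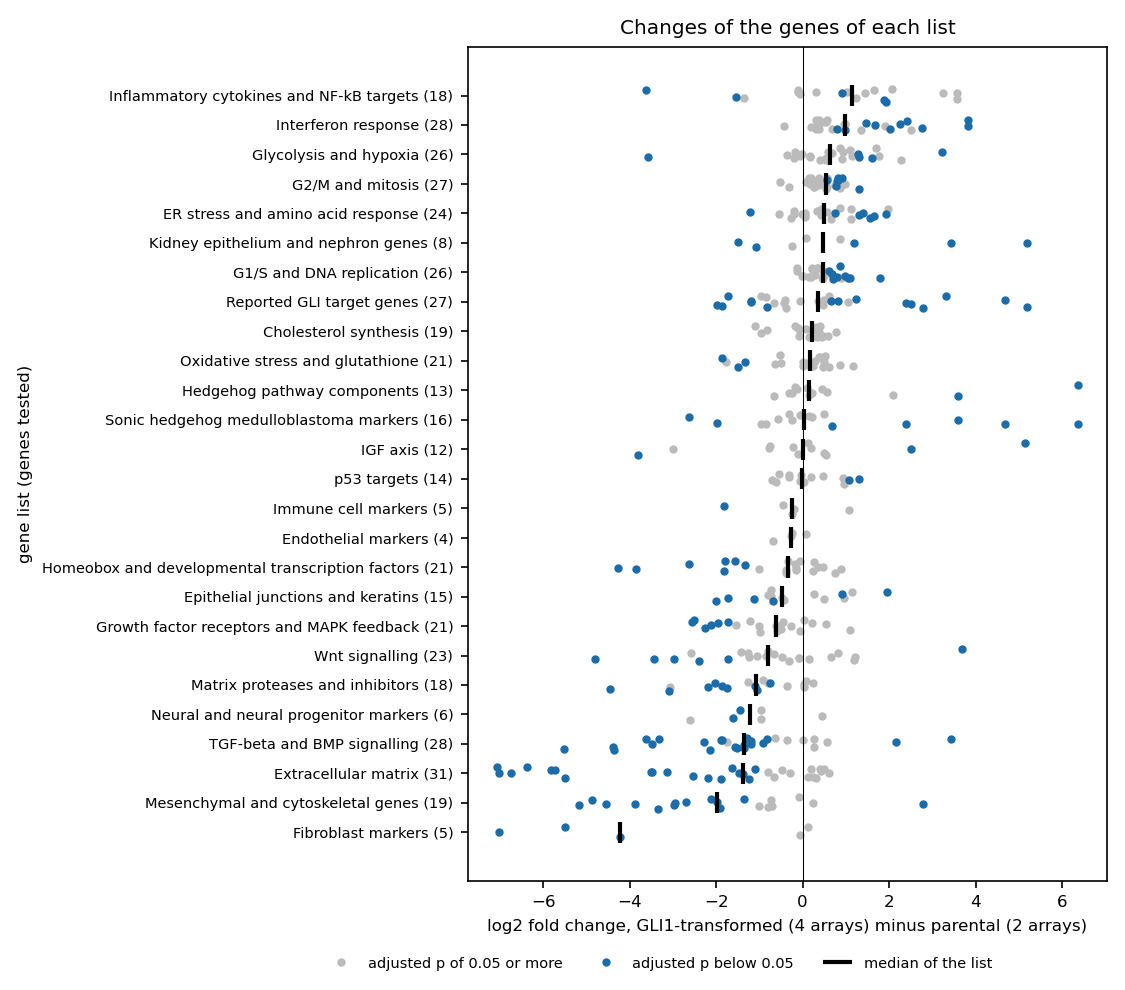
Log2 fold change of GLI1-transformed minus parental cells (horizontal axis) for each tested gene of the 26 lists, with the number tested in parentheses; blue points have adjusted p under 0.05 and black bars mark medians. Medians run from -4.22 for fibroblast markers to 1.13 for inflammatory genes.

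Clone II was the only clone with 2 labelled arrays, and a 3-level model asked how it and the other GLI1 arrays, clone I and the array with no clone named, differ. The complement gene C3 was 78.7-fold higher in clone II, with 2 arrays each (log2 difference 6.30, SE 0.50, adjusted p = 0.00722). It was at 14.11 in clone II, 7.81 in the other GLI1 arrays and 7.40 in parental cells. Ogn, a small proteoglycan gene, was higher by 3.98 (11.70 against 7.73, adjusted p = 0.00177) and lay below its parental level of 13.93 in both. The keratin gene Krt8 was lower in clone II by a log2 difference of -3.17 (9.15 against 12.32, adjusted p = 0.0157), with a parental level of 10.24. The Notch pathway gene Dtx4 gave 3.30 (0.0157), Rpp25 -4.73 (0.0157), the imprinted gene Phlda2 -4.19 (0.0371), Flrt1 -4.05 (0.0436), Pou3f1 -3.96 (0.0436) and the cytochrome gene Cyp1b1 -3.13 (0.0436).

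Between clone II and the other GLI1 arrays 24 of 18625 probe sets passed, 3 higher and 21 lower in clone II, against 1611 at an unadjusted p under 0.05. That count was 89 with the replicate number as a block, 37 with median centring, 11 with no filter, 10 with quantile normalization, and 4 both without the intensity trend and with the filter at the 60th percentile. The labels do not say that replicate numbers pair arrays. The 3 higher probe sets are those of C3, Ogn and Dtx4. Of the 9 named genes, Ogn alone kept its call with any 1 array left out. The number passing was 1 without the array that has no clone named, 94 without clone I, 10 without clone II replicate 1, and 3 without clone II replicate 2 or either parental array. Against parental cells, 743 probe sets rose and 1069 fell in clone II (4706 at an unadjusted p under 0.05), and 1038 rose and 1272 fell in the other GLI1 arrays (5220). The 1812 calls of clone II became 1147 without the intensity trend, 746 and 967 without its replicates 1 and 2, and 414 and 573 without parental replicates 1 and 2. The 2310 calls of the other GLI1 arrays became 633 and 925 without parental replicates 1 and 2. These comparisons share the parental arrays, so their overlap is not reported, and the direct contrast above tests the difference. Of the 26 lists, 13 were called between clone II and the other arrays with the preset correlation and 0 with an estimated one (adjusted p of 0.441 or more), among them the epithelial list, whose median was -0.41 (camera adjusted p = 3.65e-06), and the glycolysis list, with -0.46 (1.13e-05).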

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

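The tests of array quality and of clones were planned; the tests of the 3 patterns weighed here were chosen after the results were seen, except the matched random lists and the question of cloned cells without GLI1.

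Among the 4 GLI1 arrays, 11 of 122 measures had 1 array far from the rest by Dixon's ratio (above its 95% critical value for 4 arrays), where 6.1 would be expected by chance at 1 in 20. Clone II replicate 1 stood highest in the beta-actin 3'/5' ratio (0.914), the GAPDH 3'/5' ratio (0.886) and Gli2 (0.884), and lowest in Ankrd1 (0.863). The array with no clone named stood highest in median signal (0.899) and Sesn2 (0.8294) and lowest in Isg15 (0.869) and Tnfaip3 (0.8295). Clone II replicate 2 stood highest in Fn1 (0.880), Eya1 (0.837) and Tgfb2 (0.834).

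Clone II differed from the other GLI1 arrays, by the contrast itself, in C3 (6.30), Ogn (3.98), Dtx4 (3.30), Rpp25 (-4.73), Phlda2 (-4.19), Flrt1 (-4.05), Pou3f1 (-3.96), Krt8 (-3.17) and Cyp1b1 (-3.13), log2 differences with 2 arrays a side. Ogn alone kept its call with any 1 array left out, which leaves 1 array in a group. C3 lost its call only without the array that has no clone named, and each of the other genes without several arrays in turn. By list medians, clone II was lower for reported GLI targets (-0.28), medulloblastoma markers (-0.50), epithelial genes (-0.41), matrix (-0.32), the IGF axis (-0.80), Wnt (-0.35), MAPK feedback (-0.46), glycolysis (-0.46), ER stress (-0.31) and fibroblast markers (-1.35). It was higher for interferon (0.51), inflammatory (0.66) and cholesterol synthesis genes (0.23). The fibroblast marker Ogn, higher in clone II by 3.98, went against its list's median. None of these 13 lists was called with an estimated correlation (26 lists tested). Against the parental mean the interferon median was 0.54 on the array with no clone named, 1.46 on clone I, and 0.95 and 1.11 on clone II. The matrix median was -1.02, -1.74, -1.54 and -1.20 in that order. Clone I lay above both clone II arrays for interferon and below both for matrix, so clone I did not share either direction.

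The matrix list had a median of -1.37, while the median of all tested probe sets was 0.005. A uniform scaling shift would move all probe sets alike, so these medians argue against such a shift as the whole cause. Median centring gave -1.21 for the list, but it moves every difference by the same amount and so could not test this. RNA integrity as the whole cause is argued against too: the array of highest GAPDH 3'/5' ratio differed from that of lowest ratio by a median of -0.34 within GLI1 arrays (both of clone II) and 0.03 within parental arrays, while the 3 GLI1 arrays of lower ratio differed from the parental array of lowest ratio by -1.53 to -1.003. Loss of fibroblasts mixed into the parental culture stays open, since of 8 fibroblast markers outside the matrix list only 1 (Ogn, log2 13.93) was bright in parental cells, yet 4 of the 8 were lower in GLI1 cells by over 0.5 and most were dim, and Pdgfra was at 9.95 in parental and 9.89 in GLI1 cells. Isolation of single foci, whatever GLI1 did, cannot be told apart from GLI1, because the number of arrays of cloned cells without GLI1 was 0. A response of RK3E cells to GLI1 may account for the fall, and is a hypothesis that these arrays leave untested.

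The interferon list had a median of 0.97, while arrays of highest and lowest GAPDH ratio differed by -0.10 within GLI1 and -0.03 within parental arrays, and GLI1 arrays of lower ratio lay 0.53 to 1.44 above the parental array of lowest ratio, which argues against RNA integrity as the whole cause. Immune cells in the cultures stay open: the median difference of 16 immune markers, clone II minus parental, was 0.40 (quartiles -0.56 and 0.68) against 0.96 for the interferon list, and 0 of the 16 were bright in clone II. A difference between clones also stays open, since 0 of 28 genes differed between clone II and the other GLI1 arrays but the clone of the lowest array is not named. A GLI1 response, or a cell response to introduced DNA, could raise these genes; neither was tested.

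The rise of replication and mitosis genes had a median of 0.49 over 53 genes. It was above the highest of 10000 random lists matched on signal (0.469), at percentile 100, and 95% of these lay between -0.006 and 0.296. That argues against brightness alone as the cause. The random genes were drawn without regard to correlation, so the percentile does not allow for cell cycle genes moving together. With an estimated correlation neither list was called (camera adjusted p = 0.225 for replication and 0.515 for mitosis). Arrays of highest and lowest GAPDH ratio differed by -0.06 within GLI1 and -0.11 within parental arrays, and GLI1 arrays of lower ratio lay 0.24 to 0.57 above the parental array of lowest ratio, which argues against RNA integrity as the whole cause. Culture density at harvest was not tested and stays open. Faster cycling of GLI1-transformed cells is a possible explanation, held as a hypothesis.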

How the results depend on the processing

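All alternatives were planned except the GAPDH 3'/5' covariate and leaving out the 2 arrays of highest ratio, which were chosen after seeing the data. The called named genes were picked by their changes in these same data, so signs that hold below are no separate support. Signs held for each of the 100 called named genes: 48 lost the call with 1 array left out (47 without parental replicate 1, 38 without parental replicate 2), 8 under another scaling, offset or filter, 54 without the 2 arrays of highest GAPDH ratio and 2 (A2m and Tnfaip6) with the covariate, whose group means were about equal (1.24 and 1.20), so that it could not move the comparison much. Named genes also lost the call with the replicate block (4: A2m, Lrp2, Ogn and Nes), clone II averaged (5: A2m, Nfkb2, Dnajb9, Lrp2 and Nes), robust estimation (2: A2m and Ogn), no trend (7) and a 2-fold minimum (9). With 1 parental array left, that array is assumed to vary like the others. Such fits hold fewer arrays, which widens the SE at the same spread, so a lost call there need not mean a smaller change. The matrix list's median ran from -1.47 to -1.20 with 1 array left out in turn. For Gstm2 the log2 change went from -1.88 to -1.19 without parental replicate 2. How much of the loss of calls comes from the fewer arrays was not tested. With 1 probe set per gene, 10240 genes were tested in place of 18625 probe sets, so that smaller count below is not by itself a loss of calls. For GLI1-transformed against parental cells, 1087 risen probe sets became 705 without the trend, 617 with a 2-fold minimum, 228 to 1377 with 1 array left out and 145 without the 2 arrays; 1351 fallen became 866 with 1 probe set per gene, 282 to 1653 and 167. The 1812 calls of clone II against parental became 1147 without the trend and 414 to 2157 with 1 array left out, and the 2310 of the other GLI1 arrays 633 to 2102. The 24 of clone II against the other GLI1 arrays became 10 with quantile normalization, 37 with median centring, 11 with no filter, 4 at the 60th percentile, 4 without the trend and 1 to 94 with 1 array left out.

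With the replicate number as a fixed term (replicate block), calls numbered 1190 risen and 1437 fallen, 2537 for clone II, 3224 for the other GLI1 arrays and 89 between them. The labels do not say that the numbers pair arrays, and deviations of same-numbered arrays correlated at -0.03, 0.16, 0.32 and 0.16.

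With an estimated correlation no list was called, at medians of 0.47 (replication), 0.55 (mitosis), -1.97 (mesenchymal), -1.37 (matrix), -1.08 (proteases), -0.80 (Wnt), -1.35 (TGF-beta), -0.62 (MAPK), 0.97 (interferon), 0.64 (glycolysis), 0.49 (ER stress), -0.35 (homeobox), -4.22 (fibroblast) and -1.21 (neural). Fry did not call glycolysis (0.64) or ER stress (0.49), both at adjusted p = 0.158, and called Hedgehog (0.14) and kidney (0.47). ER stress was not called with quantile normalization (0.50) or without the array that has no clone named or parental replicate 2 (both 0.45; 0.39 to 0.61 over any 1 array left out). Neural markers were not called with no filter (-0.34), log2(value + 32) (-0.94) or without parental replicate 2 (-1.30; -1.30 to -1.16 over any 1 array), nor Wnt at the 60th percentile (-0.33), where endothelial and immune lists had no tested genes. Signs turned for uncalled Hedgehog genes near 0: Stk36 (0.034 quantile, 0.035 median centring, 0.19 without the 2 arrays, -0.31 to 0.059 with 1 array left out), Boc (0.088 without the 2 arrays, -0.72 to 0.066), Kif7 (-0.026 to 0.20), Sufu (-0.35 to 0.023) and Spop (-0.060 to 0.47). No detection calls were used, so how far dim signals lie above background is unknown.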

Other observations

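The gene families below were chosen and tested after the data were seen, as families of at least 8 tested genes sharing a symbol stem. Of 172 families 11 were called with the preset correlation and 0 with an estimated one (adjusted p of 0.776 or more). Of 46 tested mitochondrial ribosome large subunit genes (Mrpl), 9 rose and 0 fell, with a median log2 change of 0.57 (camera adjusted p = 0.000367; 0.79 with an estimated correlation), and of 27 small subunit genes (Mrps) 7 rose and 0 fell, with a median of 0.53 (0.000607; 0.776). Of 31 cytosolic large subunit genes (Rpl), 3 rose (Rpl7, Rpl4 and Rpl35), with a median of 0.48 (0.00312, and 0.79 with an estimated correlation) that was 0.24 with quantile normalization. Genes of the Rps stem (20 tested) were not called (adjusted p = 0.275), and their called members were the kinase genes Rps6ka6 and Rps6ka4. Those of the Eef stem (10 tested), which holds elongation factors, were not called either (0.332). Genes of the Eif stem had 9 of 49 risen, among them Eif4ebp1 and Eif4ebp2, which encode repressors of translation initiation, and a median of 0.43 (0.0073). Those of the Ddx stem, RNA helicases, had 5 of 32 risen and a median of 0.37 (0.0217). Both calls were lost with an estimated correlation (0.776). Of 29 tested RNA polymerase genes (Polr stem), 6 rose, and the stem's median was 0.42 (0.0073, and 0.776 with an estimated correlation). The 6 were Polr1a, Polr1b, Polr1d, Polr1e, Polr1f and Polr1h, which encode parts of or partners of RNA polymerase I, the enzyme that transcribes ribosomal RNA. That grouping was seen among the called members, and the Polr1 genes were not tested as a set of their own.

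Families called lower were the secreted Adamts proteases (4 of 9, median -0.91, camera adjusted p = 0.00312), mannosidases (5 of 8, among them Man1a1 and Man2a1, -0.83, 0.0073), phosphodiesterases (4 of 11, -0.82, 0.016), myosins (4 of 10, among them Myo1e and Myo10, -0.67, 0.0217) and Smad genes (Smad1, Smad3, Smad6 and Smad7 of 8, -0.72, 0.0412). These calls were all lost with an estimated correlation. None of the 11 medians changed sign with quantile normalization. Median centring moves every difference by the same amount, which was smaller than each of these medians, so it could not turn their signs.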
